A study of Homo sapiens with 2 samples.

How the data were processed

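Gene expression was measured in RKO cells, an established human colon cancer line, on 2 arrays. One array held RNA from cells carrying a control hairpin against luciferase (sh-Luci) and the other RNA from cells carrying a hairpin against the L form of BCLAF1. Both cultures were infected with retrovirus and selected with puromycin, per the labels. Total RNA was extracted with Trizol, and biotinylated cRNA was prepared with an Affymetrix kit that primes from the 3' end of transcripts, per the labels' protocols. Each group therefore had 1 array and no replicate, and neither a spread between cultures nor a p-value was computed.

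The deposited values are linear probe set intensities, 1 per probe set and array. The submitters' processing notes name RMA, a method that subtracts background, equalises the intensity distributions of the arrays and summarises the probes of each probe set. The program, the software version, the final scaling and the reason for the lowest deposited intensity of exactly 1 are not given in the sources used here. That value was reached by 11 probe sets on the control array and 16 on the knockdown array. Background that remains in dim probe sets would compress their folds. This was tested only for a background common to the BCLAF1 probe sets, and no detection calls were used. The number of arrays limits the precision.

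The table held 54675 probe sets. The probe annotation used here gave 1 gene symbol for 41097 of them, several for 1801 and none for the remaining 11777, which include the control probe sets. Symbols were updated through Entrez gene identifiers in a RefSeq gene table of assembly GRCh38.p14, which held 41043 of the 41097 probe sets' genes. No genomic coordinates are printed because no source used here names a build for the probe sets. The fixed gene lists held 792 entries, of which 708 had a probe set with 1 symbol, and the others were not analysed here.

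Intensities were transformed as log2(value + 1), and a difference is the knockdown minus the control. The test design, fixed before the data were examined, had assumed log2 values and named this transformation for the case of linear ones. A fold is 2 to the power of that difference. A gene took the value of its probe set with the highest mean over both arrays, among probe sets with 1 gene symbol. A gene was called detected when that mean reached the 40th percentile of all probe sets, which corresponds to an intensity of 63.7. This left 14507 of 19777 genes, of which 7755 had a single detected probe set. Counts were taken at 2-fold, with 1.5-fold and 3-fold as alternatives. Technical error was estimated only from probe sets of the same gene, as the pooled within-gene SD of the differences over 6752 genes with at least 2 detected probe sets. That SD was 0.16 on the log2 scale, or 1.12-fold, and it does not cover the spread between cultures, infections or arrays.

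For each of 29 gene lists fixed before the data were examined, the median difference of the detected members was placed among the medians of 10000 random lists of the same size, matched on mean intensity in 20 bins of equal size. A list was described as apart from the random lists below the 2.5th or above the 97.5th percentile. Genes are not replicates, so these percentiles describe this pair of arrays. Genes were named by a rule fixed at the same time. It took every BCLAF1 probe set; THRAP3, SRSF10 and a further gene not analysed here; the 12 detected genes with the largest difference in each direction among genes whose detected probe sets all differed the same way, leaving out clone and open reading frame names; and up to 4 members of each list at or past 1.5-fold. Genes named outside this rule as examples of a list or as probe sets that disagree were chosen after their values were seen.

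The procedure was tested on simulated data. The real mean intensities received noise with the within-gene SD, and 200 of the 19777 genes received known changes. Of 50 genes changed 3-fold, 50 were recovered past 2-fold in the right direction, against 23 of 50 changed 2-fold and 1 of 50 changed 1.5-fold. None of 14307 unchanged detected genes passed 2-fold and 3 passed 1.5-fold. Of 100 unchanged lists of 25 genes, 1 lay outside the central 95% of random lists, against 68 of 100 shifted by -0.1 and 100 of 100 shifted by -0.4. The simulated noise was independent between probe sets and equally large for bright and dim ones. It held no spread between cultures, infections or arrays, so these counts do not give the error rates of the real arrays.

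The alternatives were the median over all probe sets of a gene, leaving out probe sets with _s_at or _x_at names, no filter on low values, a filter at the 60th percentile, subtraction of the median difference, subtraction of a loess curve of the difference on the mean (span 0.3), other fold thresholds and unmatched random lists. A pseudocount of 32 and random lists drawn from protein-coding genes or from the other gene lists were added after seeing the data, as was 1 list without members that another list also held. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9. Exact binomial intervals are Clopper-Pearson intervals at 95% and cover counting error only.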

Results

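The transcriptome of RKO colon cancer cells was profiled after knockdown of BCLAF1-L, the long form of the nuclear protein BCLAF1, and compared with that of cells carrying a luciferase hairpin. The comparison asks which transcripts differ between cells with these hairpins. No other hairpin against BCLAF1 was measured, so lower BCLAF1 and other effects of the hairpin cannot be told apart. Each group was represented by 1 array, so all values below are single measurements without a replicate check, and no p-value is given. The deposited intensities ranged from 1 to 17349 on the control array and from 1 to 16650 on the knockdown array, with medians of 82.7 and 84.5. The log2 intensities of the 14507 detected genes correlated across genes with Pearson's r = 0.994. Their log2 differences had an SD of 0.17, and the central 95% lay between -0.31 and 0.37. Probe sets of the same gene differed from each other with an SD of 0.16 on the log2 scale.

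BCLAF1 mRNA was lower in the knockdown on all 6 of its probe sets, and BCLAF1 had the lowest log2 difference of the 14507 detected genes. Its brightest probe set read 2505 in the control and 945 in the knockdown, a 2.65-fold lower intensity that left 37.7% of the control value. The probe sets that read 1765 and 694 in the control were 2.59-fold and 2.96-fold lower. The difference was smaller on the probe set at 551 in the control, which was 1.88-fold lower, and on those at 231 and 111, which were 1.43-fold lower each. The median over the 6 probe sets was 2.21-fold lower. Which of the BCLAF1 forms each probe set reads is not given in the sources used here, so these values check the knockdown of BCLAF1 transcripts and not of the L form alone.

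THRAP3, the closest relative of BCLAF1, had a brightest probe set that was 1.34-fold higher (798 and 1071), and its 3 detected probe sets differed by 0.05 to 0.42 on the log2 scale. A further probe set, which lay below detection, differed by -0.24, and the median over all 4 was 0.057. SRSF10, a splicing regulator, read 1199 and 1123, and its 5 probe sets spread from -0.16 to 0.18.

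Few other transcripts differed by 2-fold. Among detected genes, 10 were at least 2-fold higher and 1, BCLAF1 itself, was at least 2-fold lower. At 1.5-fold, 63 genes were higher and 29 lower. The share of higher genes at that threshold was 68.5%, and it was 56.8% (54 higher and 41 lower) when the median difference of all probe sets, 0.026, was subtracted. The counts at 1.5-fold depended on the treatment of dim and multiple probe sets, with 33 higher and 18 lower for the median over probe sets, 34 and 20 with a filter at the 60th percentile, 32 and 13 with a pseudocount of 32, and 235 and 117 without a filter. At 2-fold, 6 genes were higher with the median over probe sets or the larger pseudocount, and 35 were higher and 10 lower without a filter. Where a second detected probe set of a gene past 1.5-fold existed, it differed in the same direction in 22 of 28 genes, or 78.6% (exact 95% interval 59.0% to 91.7%). All detected probe sets went the same way in 13 of 19 such higher genes and 5 of 9 such lower genes. The remaining 44 higher and 20 lower genes had 1 detected probe set and could not be checked this way.

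The genes named for the largest higher values in the knockdown differed in brightness and in how far their probe sets went together. MMP1, the interstitial collagenase, was 3.01-fold higher (145 and 440). SPRY2, a feedback inhibitor of receptor tyrosine kinase signalling, was 2.33-fold higher (529 and 1233). AKAP12, a scaffold protein that anchors protein kinase A, was 2.10-fold higher (1078 and 2264), with differences of 0.85 to 1.07 on its 3 detected probe sets. PDP1, the catalytic subunit of a pyruvate dehydrogenase phosphatase, was 1.90-fold higher (1156 and 2191), and its other probe set differed by 0.95. ACYP1, an acylphosphatase, was 2.10-fold higher (331 and 696). FZD4, a Frizzled receptor, was 1.98-fold higher (165 and 328). MMP1, SPRY2, ACYP1 and FZD4 each rested on 1 detected probe set.

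The other genes named at this end were dimmer or less uniform. Of these, PIWIL4, ADAMTS6, ADAM21, ITPRIPL1 and MIR100HG each rested on 1 detected probe set. PIWIL4, an Argonaute family member, read 42.5 and 147 and was 3.40-fold higher. ADAMTS6, a secreted metalloproteinase, read 42.0 and 99.2. ADAM21 read 56.2 and 103. All 3 lay below the detection intensity of 63.7 in the control, so their folds rest on a value near background. ITPRIPL1 was 2.28-fold higher (67.1 and 154), and the non-coding transcript MIR100HG was 2.18-fold higher (104 and 229). EPB41L4B was 2.09-fold higher on its brightest probe set, whereas its other detected probe sets differed by 0.08 and 0.23. With the median over all probe sets of a gene, EPB41L4B, ADAMTS6 and ADAM21 differed by 0.084, 0.54 and 0.49, under 1.5-fold, and MIR100HG by 0.60 instead of 1.13. The remaining gene past 2-fold, ZNF148, was 2.01-fold higher on its brightest probe set, but 3 of its 6 detected probe sets differed the other way.

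**Figure D1:**
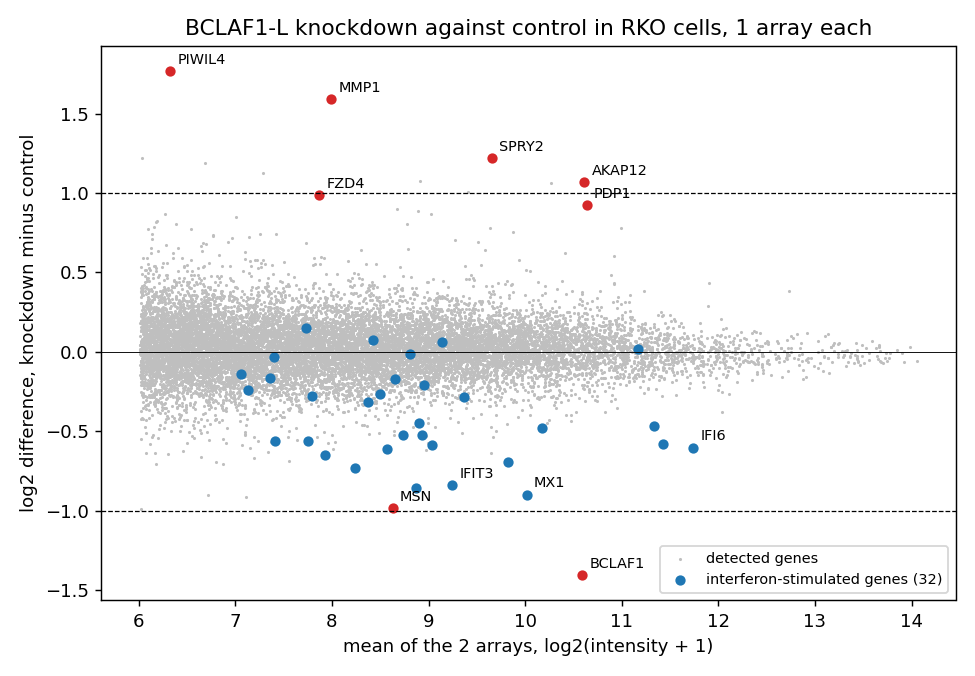
Log2 difference between knockdown and control against the mean log2(intensity + 1) of the 2 arrays for every detected gene (grey). The 32 interferon-stimulated genes are in blue, other labelled genes are in red, and dashed lines mark 2-fold; BCLAF1 lies lowest and 28 of the 32 blue points lie below 0.

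Interferon-stimulated genes were lower in the knockdown as a group. Of the 32 detected members of this list, 28 had a negative difference, with a median of -0.46 on the log2 scale (quartiles -0.59 and -0.17), a ratio of 0.728 to the control. Of these members, 18 lay among the lowest 2.5% of all detected genes, where 0.8 would be placed by chance, and none among the highest 2.5%. At least 1.5-fold lower were 8 members, and none was 1.5-fold higher. The median lay below all 10000 matched random lists, of which the central 95% ran from -0.046 to 0.071.

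MX1, a dynamin-like antiviral GTPase, was 1.87-fold lower (1414 and 757). IFIT3, of the family of antiviral proteins with tetratricopeptide repeats, was 1.79-fold lower (810 and 452), and its second probe set differed by -0.53. IRF7, the transcription factor of type I interferon production, was 1.66-fold lower (389 and 234). IFIT1 was 1.62-fold lower (1154 and 713). IFI44 was 1.81-fold lower on its brightest probe set (629 and 347), while its second probe set read 196 and 197. Abundant members were lower too. IFI6 went from 4217 to 2776, and the ubiquitin-like modifier ISG15 from 3377 to 2257. IFIH1, a cytosolic sensor of double-stranded RNA, was 1.57-fold lower, and the oligoadenylate synthetase OAS1 1.53-fold lower. On its brightest probe set, the related OAS2 differed by -0.01, BST2 by 0.02, ISG20 by 0.06, PARP9 by 0.07 and IRF1 by 0.15. The second-brightest probe sets of OAS2, ISG20, PARP9 and IRF1 differed by -0.27, -0.058, -0.41 and -0.19, and BST2 had 1 probe set. Over all 50 detected probe sets of the 32 members, 44 were lower, and of 15 members with several detected probe sets, 10 were lower on each of them. The other 17 members had 1 detected probe set, among them MX1, IRF7, IFIT1, IFIH1, IFI6 and ISG15.

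**Figure D2:**
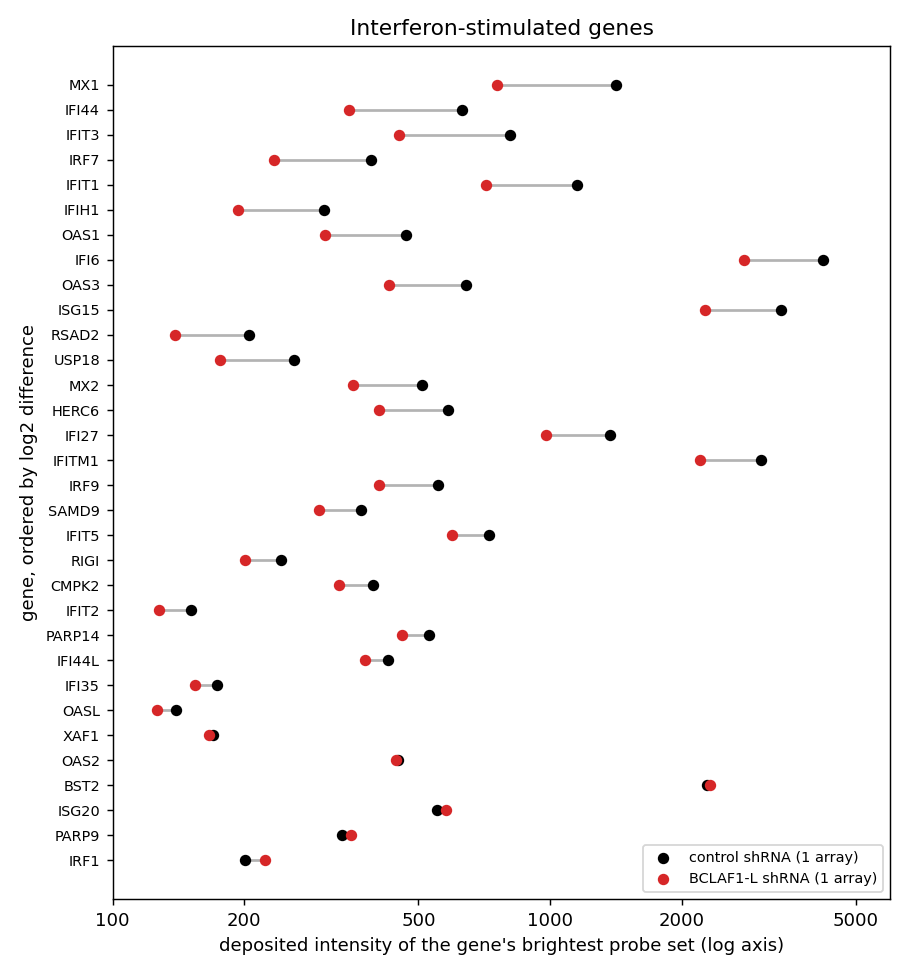
Deposited intensity (log axis) of the brightest probe set of each of the 32 detected interferon-stimulated genes, with 1 array of control cells (black) and 1 of knockdown cells (red). MX1 at the top went from 1414 to 757, and 4 genes at the bottom were higher in the knockdown.

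Outside the interferon list, the genes named for the largest lower values after BCLAF1 each rested on 1 detected probe set. MSN (moesin, which links the plasma membrane to actin) was 1.98-fold lower (556 and 281). KLHL31 was 1.88-fold lower (189 and 99.8), CCDC178 1.87-fold (143 and 76.1), and the hyaluronan-binding protein CEMIP 1.63-fold (148 and 90.5). SFTA1P was 1.62-fold lower (141 and 86.8). ADGRE2, an adhesion G protein-coupled receptor, read 90.8 and 45.2, and the gel-forming mucin MUC5B read 91.4 and 55.5, so their knockdown values lay below the detection intensity. With the median over all probe sets of a gene, undetected ones included, the differences of MSN, KLHL31, CEMIP, MUC5B and ADGRE2 were under 1.5-fold, at -0.48, -0.41, -0.19, -0.31 and -0.58. TAGLN, an actin-binding protein named as a member of the mesenchymal list, was 1.61-fold lower on its brightest probe set and differed by -0.87 and 0.15 on its other probe sets.

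Of the 29 gene lists, 6 had a median below the 2.5th percentile of random lists and none lay above the upper limit, where 1.45 lists would be placed outside by chance. That number takes the genes of a list as independent of each other. Some lists also share members: HSPD1 and HSPE1 are in the MYC target and heat shock lists, and BAX and PMAIP1 in the p53 target and BCL2 family lists. In the 5 lists other than the interferon list, no member reached 1.5-fold. The replication-dependent histone genes had a median of -0.14 (13 members, percentile 0.175), the MYC target genes of -0.096 (24 members, percentile 0.01) and the heat shock response genes of -0.085 (15 members, percentile 0.29). For p53 target genes it was -0.074 (25 members, percentile 0.40) and for BCL2 family apoptosis genes -0.071 (18 members, percentile 0.97). Among MYC targets, 21 of 24 members were lower, including MYBBP1A at -0.42 and RRP9 at -0.35, whereas MYC itself differed by 0.07. Among p53 targets, MDM2 differed by -0.29, CDKN1A by -0.14 and PPM1D by 0.32. In the BCL2 family, the anti-apoptotic BCL2A1 differed by -0.43, the pro-apoptotic BAD by -0.25 and BCL2 by 0.23. Without probe sets that can match several transcripts, the medians of the histone, heat shock, p53 target and BCL2 family lists lay inside the random range (percentiles 4.16, 4.31, 9.86 and 42.2). In that setting the heat shock median itself was unchanged at -0.085, over 8 instead of 15 members, and the BCL2 family median was 0.0079. The BCL2 family median was also above 0 with the median over probe sets (0.0015). Against members of the other gene lists, the p53 target and BCL2 family lists lay at percentiles 2.77 and 6.07.

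The cell cycle lists did not stand apart. The median was -0.023 for 34 G1/S and DNA replication genes, 0.023 for 35 G2/M and mitosis genes and -0.060 for 14 G1 cyclins, CDKs and CDK inhibitors, the last at percentile 3.17. In the last list, cyclin D1 (CCND1) differed by -0.44 (738 and 543) and the CDK inhibitor CDKN2A by 0.45 (69.2 and 95.1). The medians of the death receptor and caspase genes (-0.031), the DNA damage response genes (0.026) and the SR proteins and splicing regulators (-0.031) also lay inside the range of random lists. So did those of the MAPK output genes (-0.023), in which SPRY2 differed by 1.22, DUSP6 by 0.36 and FOSL1 by -0.50, and the mesenchymal genes (0.0071), in which 12 members were higher and 12 lower.

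The metabolic, stress and signalling lists also lay inside the random range, with exceptions under other settings. Medians were 0.0009 for respiratory chain genes, 0.0002 for hypoxia and glycolysis genes, -0.023 for cholesterol synthesis genes, -0.018 for ribosomal protein genes and -0.0055 for NRF2 targets. They were 0.026 for unfolded protein and integrated stress response genes, -0.018 for NF-kB and inflammatory genes, 0.018 for TGF-beta and BMP targets, 0.041 for Wnt and intestinal stem cell genes, 0.010 for autophagy and lysosome genes and 0.023 for epithelial junction genes. The NF-kB list lay outside the range with the median over probe sets (-0.081, percentile 0.96), the respiratory chain list without probe sets that can match several transcripts (-0.047, percentile 2.44), and the ribosomal protein list against members of the other gene lists (percentile 98.8). Markers of other cell types lay inside the random range, with medians of 0.097 for 8 fibroblast markers, 0.029 for 7 blood cell markers and -0.0040 for 5 endothelial markers. So did the 12 colonocyte and goblet differentiation markers, with a median of 0.068. Most of these 12 were dim, and 3 of them passed a filter at the 60th percentile. The blood cell marker median was 0.032 without a filter. It was below 0 with the median over probe sets (-0.099) and without probe sets that can match several transcripts (-0.11). With a filter at the 60th percentile it was -0.25 over 5 markers and lay at percentile 0.07, outside the range.

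**Figure D3:**
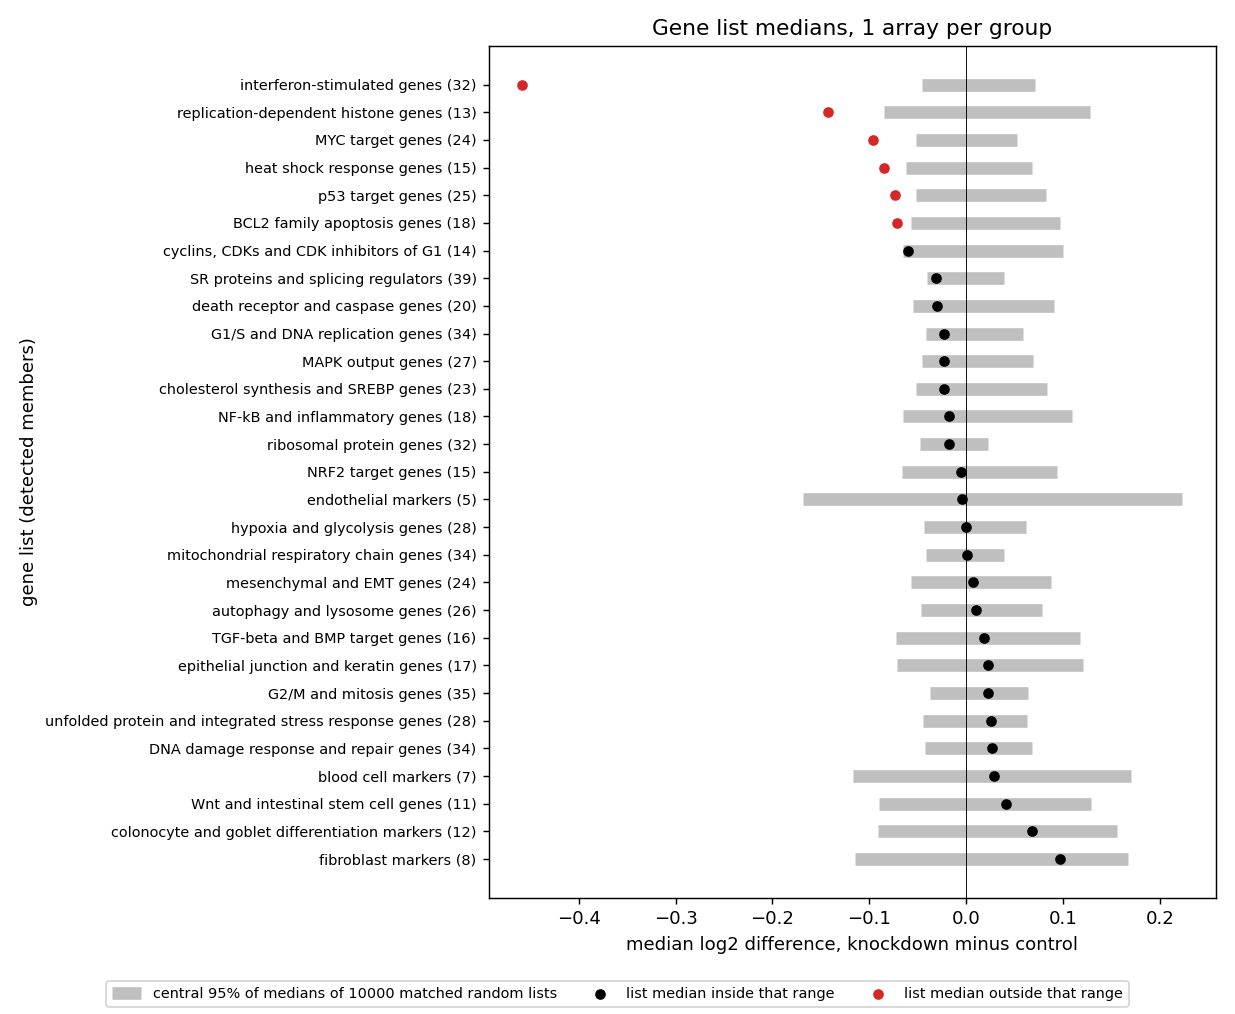
Median log2 difference of the detected members of each of the 29 gene lists (points; number of members in brackets) over the central 95% of medians of 10000 random lists matched on intensity (grey bars). The interferon-stimulated genes at -0.46 lie far to the left of their bar, 5 further lists (red) lie between -0.14 and -0.071, and the other points (black) lie inside their bars.

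Control probe sets differed between the arrays. The ratio of the 3' to the 5' probe set, a measure of RNA integrity and labelling, was 3.41 for ACTB on the control array and 3.81 on the knockdown array, and 1.38 and 1.49 for GAPDH. All 18 probe sets of the bacterial biotin spike-ins were higher on the knockdown array, with a median difference of 0.20 (0.05 to 0.33). The 24 probe sets of the Bacillus poly-A controls had a median of -0.015 (-0.21 to 0.19). In size, the spike-in median exceeded the medians of the gene lists other than the interferon list, such as -0.14 for the histone genes. With 1 array per group, a difference between the arrays and a difference between the hairpins cannot be told apart.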

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

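Probe sets to which the annotation used here gives no gene symbol entered no gene comparison. Of 5059 such detected probe sets, 3 were at least 2-fold higher on the knockdown array than on the control array. They read 53.7 in the control and 131 in the knockdown, 121 and 290, and 80.0 and 172. In the other direction, 5 such probe sets were at least 2-fold lower, of which the lowest read 884 and 289 (log2 difference -1.61). No explanation was tested for them.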

How the results depend on the processing

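No paired analysis was possible because each group had 1 array, and no replicate could be left out. The pseudocount of 32 and the random lists from protein-coding genes or the other gene lists were chosen after seeing the data. The interferon-stimulated genes stayed below all random lists in every setting, with medians between -0.48 and -0.32. BCLAF1 stayed past 2-fold except without _s_at and _x_at probe sets, where the remaining brightest probe set gave -0.51. The count of genes at least 2-fold higher was 6 with the median over probe sets, 6 with a pseudocount of 32, 35 without a filter, 63 at 1.5-fold and 2 at 3-fold. The count lower was 0 without _s_at and _x_at probe sets, 10 without a filter, 3 after median subtraction, 2 after loess, 29 at 1.5-fold and 0 at 3-fold. The second probe set agreed in 75% of 4 genes past 2-fold, in 62.5% of 8 without a filter, and in 100% of 3 after median subtraction, loess or the larger pseudocount.

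With the median over probe sets, the BCL2 family median reversed to 0.0015, the NF-kB list lay at percentile 0.96 (median -0.081), and medians were 0.026 for cholesterol synthesis, 0.054 for NRF2 targets and -0.099 for blood cell markers. Without _s_at and _x_at probe sets, the BCL2 family reversed to 0.0079; p53 targets (-0.042), histones (-0.097) and heat shock genes (-0.085, from 8 instead of 15 members) came inside the random range; and medians were 0.076 for death receptors and caspases, 0.015 for splicing regulators, 0.012 for ribosomal proteins, -0.047 for the respiratory chain (percentile 2.44, outside the range), 0.055 for cholesterol synthesis, 0.10 for TGF-beta targets, -0.064 for autophagy and -0.11 for blood cell markers. At the 60th percentile, medians were -0.050 for NRF2 targets, -0.061 for epithelial genes, -0.25 for 5 blood cell markers (percentile 0.07, outside the range) and -0.097 for 3 colonocyte markers. Median subtraction shifts every list alike, to -0.049 for G1/S, -0.057 for splicing regulators, -0.044 for ribosomal proteins and -0.025 for the respiratory chain. Against members of the other gene lists, p53 targets (-0.074, percentile 2.77) and the BCL2 family (-0.071, percentile 6.07) came inside the range, and ribosomal proteins (-0.018) lay at percentile 98.8. Of the named genes, IFI44 (0.0088) and TAGLN (0.15) reversed without _s_at and _x_at probe sets. THRAP3 (0.42) and SRSF10 (-0.09) changed sign there too, to -0.24 and 0.18, and THRAP3 was 0.057 with the median over probe sets. Of the other results on named genes, 168 kept direction and side and 14 came under 1.5-fold: ADGRE2, MSN, KLHL31, IFI44, MUC5B, CEMIP, ADAM21, EPB41L4B and ADAMTS6 with the median over probe sets, ADGRE2 and EPB41L4B without _s_at and _x_at probe sets, and MUC5B, CEMIP and SFTA1P with the larger pseudocount. The cause was not tested, except that fewer probe sets enter under the stricter choices. Low signal limits PIWIL4, ADAMTS6, ADAM21, ADGRE2 and MUC5B.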

Other observations

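The tests of the BCLAF1 probe sets were chosen after their result was seen, and the gene lists in this part were chosen after the main results were seen. Further interferon-induced genes outside the fixed list were also lower in the knockdown, by less. Of 34 detected members, 29 had a negative difference, with a median of -0.14. This median lay below all 10000 matched random lists. It also lay below all random lists drawn from the fixed gene lists other than the interferon list. Examples are LAMP3, a lysosomal membrane protein (-0.54), the scramblase PLSCR1 (-0.45), the aminopeptidase LAP3 (-0.45), NMI (-0.33) and IFITM3, which restricts viral entry (-0.27). None of the 34 reached 1.5-fold. Of 15 antigen presentation genes 11 were lower (median -0.11, percentile 0.135). Among these were the peptide transporter subunit TAP2 (-0.52) and HLA-B (-0.26). The 4 higher members were TAPBP (0.32), TAP1 (0.09), PSMB10 (0.08) and PSMB9 (0.06). TAP2 and TAPBP were each lower on 2 of their 3 detected probe sets. HLA-B, HLA-C, HLA-E, HLA-F and HLA-G were all lower. HLA probe sets can cross-hybridise between HLA genes, so these may not be separate observations. In contrast, 16 genes of interferon induction and reception had a median of -0.011 (percentile 23.5), with 8 higher and 8 lower, including IRF3 (-0.28), IFNAR2 (-0.24) and MAVS (0.24). The interferon gene IFNL1 had the largest difference of this list and was higher by 0.42, from a dim 71.2 to 95.7. It lay among the highest 2.5% of detected genes. Some induction and signalling genes were in the fixed interferon list and not among these 16. They include IRF7 (-0.73), IFIH1 (-0.65), IRF9 (-0.45), RIGI (-0.28) and IRF1 (0.15), so the contrast depends on how the lists were divided.

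The lower level of interferon-stimulated genes was weighed against technical explanations. An intensity-dependent offset is argued against by the loess curve, which ran only from -0.023 to 0.035 over detected probe sets. Subtracting so flat a curve could move the list's median little, and left it at -0.47. Error of single probe sets is argued against too for the 15 members with several detected probe sets. Their second-brightest probe sets had a median of -0.27 and 13 of them were lower. The other 17 members had 1 detected probe set and could not be checked this way. The wider set at -0.14 is consistent with a lower interferon response as a whole in the knockdown culture. A difference between single cultures or arrays stays open. With 1 array per group, a higher interferon state of the control culture and an effect of the BCLAF1-L hairpin cannot be told apart. Lower BCLAF1 and other effects of that hairpin cannot be told apart either, because no other hairpin against BCLAF1 was measured.

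The BCLAF1 probe sets were lower by unequal amounts, with a range of 1.05 on the log2 scale. A background common to all 6 stays open. Subtracting the common background that brings them closest, 54.8, left an SD of 0.38, against 0.47 without it. Of 133 other genes with 6 detected probe sets, 2 had an SD at least as large as measured, and 12 when their error was enlarged as the subtraction enlarges it, so the outcome depends on how that error is treated. A candidate explanation is that the probe sets read different BCLAF1 forms and the hairpin removes one of them, which cannot be told apart from background because the probe positions were not used here.

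More genes were higher than lower past 1.5-fold (63 and 29). Error of dim probe sets may contribute, as 47.6% of the higher genes (30 of 63, exact 95% interval 34.9% to 60.6%) lay in the dimmest 25% of detected genes, but outside these 33 were still higher and 19 lower. An overall or intensity-dependent shift between the arrays stays open as part of it: the ratio of higher to lower genes was 1.56 after loess (56 and 36).

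MSN, TAGLN, CNN1, CCN2 and ENAH were among the lower genes, which prompted the hypothesis that SRF and YAP target genes and the actin cytoskeleton are lower in the knockdown. These genes and ACTB were left out of the test. In a list of 32 further detected genes of this kind, 23 were lower and 9 higher. Among them were MYL9 (-0.43), profilin PFN1 (-0.38) and PDLIM7 (0.36, though 4 of its 5 detected probe sets were lower). The median was -0.058. This median lay at percentile 0.59 of matched random lists, past the limit of 2.5 set before the test, as the hypothesis predicted for the list as a whole. The list pools SRF and YAP target genes with other actin cytoskeleton genes, so its median cannot tell these apart. The mesenchymal list of the report already held 3 of these members (CCN1, TPM1 and TPM2), and the other 29 had a median of -0.065 at percentile 0.47. The median of all 32 lay at percentile 4.43 of lists drawn from the fixed gene lists other than the interferon list, inside that limit. With no member at 1.5-fold either, the evidence is weak and has no replicate check. The 5' ACTB control probe set, which is sensitive to RNA integrity, differed by -0.44 and the 3' one by -0.28.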
